A study of Mus musculus with 9 samples.

How the data were processed

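H2A.X was profiled by native ChIP and Illumina sequencing in mouse ESC, MEF, TSC and iTSC samples, 9 samples with the input DNA. The submitters' processing notes name CASAVA, Bowtie and Bowtie2 2.1.0 and the genome build mm9, with no role or order. A two-sample hidden Markov domain caller of the RSEG kind, whose version and filters are not given in the sources used here, compared each library with TSC_B. Its deposited output is 1 list per sample, with no pooling, for ESC, MEF, TSC_A, iTSC_3F samples 1 and 14 and iTSC_4F samples 1 and 5. The TSC_B and input samples have no list of their own and are not analysed here beyond the part of TSC_B as reference.

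Each list gives a domain's position, its state, a deposited score and a deposited sum of posterior probabilities. The score is used as deposited and was read, from the values, as the mean difference in reads per bin between the sample and TSC_B, without scaling for depth. Bins were 1350 bp, and 1300 bp in iTSC_3F_1, so scores and lengths depend on the bins. No score lies between the highest of the TSC_B state and the lowest of the sample state, and this gap sits at different values, from -2.00 to -0.996 in iTSC_3F_1 and from 6.35 to 9.15 in MEF. The lists thus hold domains down to different scores, and neither the number of domains nor the covered length is a like-for-like measure between lists. Whether the gaps come from the caller's segmentation or from a filter is not given in the sources used here. Dividing the sum of posteriors by the number of bins gave the mean posterior, which was 0.485 over the sample-state domains of iTSC_3F_1 and 0.889 over the TSC_B-state domains of ESC. The numbers of reads per library are unknown, and a deeper library can give more and shorter domains.

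Samples were grouped by their labels. Coordinates are those of mm9, written 1-based. A chromosome's extent ran from the first to the last position that any list covers, 2589 Mb over all 22 chromosomes with the mitochondrial genome. Domain numbers, lengths and covered length were computed per list and state, and a chromosome was called filled where 1 state covered at least 50% of its extent. The 3-factor and 4-factor samples were compared with a two-sided exact permutation test.

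Overlap of a pair of lists in the same state was the shared length on a grid of 1 kb. It was compared with 100000 circular shifts of 1 list within each chromosome, which keep the domains' lengths, spacing and chromosome. The test was one-sided for more overlap than chance, and the smallest p it can give is 1e-05. Benjamini-Hochberg adjustment was over 42 pairs, 21 per state, with a threshold of 0.05, and was done separately for all chromosomes and for autosomes. Shifts spread domains over unmappable stretches too, so chance overlap is somewhat low wherever both lists avoid those. On simulated data with 4 pairs of lists, overlap planted in 30% of the domains was found in all 20 simulations of each pair. Without planted overlap, p fell under 0.05 in 1, 2, 1 and 0 of 20 simulations. Those lists were made with the same circular shifts as the test, so a rate near 0.05 follows from their construction. The planted domains were copied whole from the other list, which makes them easy to find. The simulations therefore check the computation only, not the effect of the shared TSC_B library or of unmappable stretches.

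The domains to be named were set by a rule fixed before the data were examined: per list and state the 5 longest and the 5 highest-scoring of at least 5 kb, and the 10 longest regions shared by all 4 iTSC samples, from which the text gives a part. That plan also named genes under these domains, tests of fixed gene lists and the position of domains relative to genes. The gene table used here is of another build than mm9 and coordinates were not converted, so domains are named by position only and no gene was assigned.

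Alternatives were a score at or above the pooled median, domains of at least 5 kb, joining within 10 kb, autosomes only, removal of domains that overlap the TSC_A list, overlap counted by domains, 1 shift of the whole genome and leaving out each iTSC sample. Those added after seeing the data were domains of at most 1 Mb, a mean posterior of at least 0.8, scores at least 1.5 from the middle of the list's gap, and pairs without MEF. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.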

Results

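The series profiled H2A.X, a variant of the core histone H2A that is best known for its phosphorylated form at sites of DNA damage, in mouse stem cells and fibroblasts. The 9 samples comprised 1 embryonic stem cell sample (ESC, from the pluripotent cells of the early embryo), 1 embryonic fibroblast sample (MEF), 2 trophoblast stem cell samples (TSC_A and TSC_B, from the lineage that forms the placenta), 4 samples of induced trophoblast stem cells (iTSC) and 1 input DNA. Of the iTSC, 2 were made with 3 factors (iTSC_3F, samples 1 and 14) and 2 with 4 factors (iTSC_4F, samples 1 and 5). Chromatin was cut to single nucleosomes with micrococcal nuclease without crosslinking (native ChIP), and nucleosomes holding H2A.X were pulled down and sequenced. The study asked how the distribution of H2A.X differs between these cell types.

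For 7 of the samples, domains that differed from the TSC_B library were available, each in 1 of 2 states. The domain caller assigned a domain to the sample state where it modelled the named sample as enriched over TSC_B, and to the TSC_B state for the opposite. The states are relative to a list's own balance point and not to equal reads: 96.2% of the MEF and 46.1% of the iTSC_3F_14 domains in the TSC_B state had a score above 0, meaning more reads in the sample, and 77.8% of the iTSC_3F_1 and 46.7% of the iTSC_4F_5 domains in the sample state had a score below 0. Gains and losses below are used in this relative sense. The lists ranged from 441 domains in iTSC_4F_1 to 33000 in MEF. The numbers of reads behind the lists are unknown, so no interval is given for any value. ESC and MEF had 1 sample each, and nothing in the labels says whether the iTSC samples came from separate cultures, so differences between single lists had no replicate check and the p-values between iTSC groups measure only the spread of these samples, which may be technical.

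ES cells had gains over TSC_B on nearly all autosomes, and losses concentrated on chromosomes X and 11. The ESC list held 456 domains in the sample state, which covered 96.9 Mb with a median length of 153 kb, and 183 domains in the TSC_B state, which covered 215 Mb with a median of 35.1 kb. The sample-state domains were spread over the autosomes, at a median of 3.88% of each autosome and at most 8.26%. The TSC_B-state domains lay mostly on chromosome X, with 128 Mb or 79.0% of its extent, and on chromosome 11, with 85.5 Mb or 71.9%. The longest gains were at chromosome 10: 29636551 to 31160700 (1524 kb), chromosome 15: 3744901 to 5233950 (1489 kb) and chromosome 1: 46051201 to 47358000 (1307 kb). All 3 also touched sample-state domains of MEF, iTSC_3F_1 and iTSC_4F_5, and those on chromosomes 10 and 1 touched TSC_A as well. Such contact was common, as only 3 of the 440 autosomal gains of ESC touched no other list. Much of it was contact with the 31116 autosomal gains of MEF, and 87 of the 440 touched no list other than MEF. No chance level was computed for contact with any list.

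Fibroblasts had by far the most domains. The MEF list held 31253 domains in the sample state, which covered 568 Mb with a median length of 10.8 kb, and 1747 in the TSC_B state, which covered 227 Mb. Its 33000 domains were 58.2 times the 567 of the TSC_A list, whereas its covered length, 795 Mb, was 1.21 times that of TSC_A. The gains had a median of 25.0% of each autosome and at most 29.4%, with the lowest share, 8.48%, on chromosome 11, where the TSC_B state covered 15.4%. The longest gain was 451 kb, at chromosome 5: 110057401 to 110508300. The TSC_B state covered 139 Mb (85.8%) of chromosome X and 13.3 Mb (83.4%) of chromosome Y in MEF. The mean score of these domains was 3.46 on X and 0.093 on Y, and 13.0 Mb of Y was 1 domain with a score of 0. Such a score cannot tell equal reads from no reads in either library, so the state on Y is no evidence of a difference. With only domains of a mean posterior of at least 0.8, a choice made after seeing the data, 10890 MEF domains over 258 Mb were left.

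The comparison of both trophoblast stem cell samples gave the background of the same cell type. The TSC_A list held 313 domains in the sample state over 637 Mb and 254 in the TSC_B state over 21.2 Mb, together 25.4% of the genome extent. Chromosome 10 was in the sample state over 126 Mb (99.3%), chromosome 2 over 123 Mb (69.0%) and chromosome 1 over 98.4 Mb (50.7%). Their mean scores were 0.795 (SD 0.139 over domains), 0.296 (SD 0.439) and 0.154 (SD 0.202). Those of chromosomes 2 and 1 lay within their SD of 0, but that of chromosome 10 did not. The covered length of TSC_A against TSC_B, 658 Mb, exceeded that of ESC (312 Mb), iTSC_3F_1 (294 Mb) and iTSC_4F_1 (241 Mb). This is no like-for-like ranking. The lowest sample-state score was 0 in TSC_A and -0.996 in iTSC_3F_1, but 1.01 in ESC and 1.00 in iTSC_4F_1. The mean scores of chromosomes 10, 2 and 1 in TSC_A lie below those of the last 2 lists. With only domains of at most 1 Mb, the order turned for ESC and iTSC_3F_1. The lengths were then 72.2 Mb in TSC_A, 96.7 Mb in ESC, 224 Mb in iTSC_3F_1 and 38.4 Mb in iTSC_4F_1. With scores at least 1.5 from the gap's middle, TSC_A covered 149 Mb, less than the 241 Mb of iTSC_4F_1, which lost no domain there. ESC then covered 41.5 Mb and iTSC_3F_1 38.1 Mb. At a mean posterior of at least 0.8, the lengths were 247 Mb in TSC_A, 213 Mb in ESC, 3.81 Mb in iTSC_3F_1 and 220 Mb in iTSC_4F_1.

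The iTSC samples varied widely in how much of the genome differed from TSC_B, and in which direction. iTSC_3F_1 had 649 domains in the sample state over 261 Mb and 385 in the TSC_B state over 33.0 Mb. iTSC_3F_14 had 596 over 394 Mb and 438 over 578 Mb. iTSC_4F_1 had 180 over 161 Mb and 261 over 79.7 Mb, and iTSC_4F_5 had 1766 over 683 Mb and 500 over 42.9 Mb. The 3-factor samples had 1034 ± 0 domains and the 4-factor samples 1353.5 ± 1290 (SD, n = 2 each), a difference of -319.5 with p = 1 in a two-sided exact permutation test. Covered length was 633 ± 480 Mb against 483 ± 343 Mb (SD, n = 2 each), a difference of 150 Mb within the spread of the samples (exact permutation p = 0.667). With 2 samples against 2 the smallest p of this test is 0.333, so no difference could pass the threshold in it. Leaving out iTSC_3F_14 or iTSC_4F_1 turned the difference in covered length to -189 or -92.8 Mb, and leaving out iTSC_4F_5 turned the difference in number to 593. With a mean posterior of at least 0.8, covered length was 3.81 Mb in iTSC_3F_1 and 40.6 Mb in iTSC_4F_5, against 294 and 726 Mb for all domains.

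Long stretches of single chromosomes set much of the covered length, and which chromosome it was differed between samples. At least 50% of a chromosome's extent was in 1 state in 14 cases, on autosomes as well as on X and Y. For none of them can a different number of copies of the chromosome be told apart from a difference in H2A.X along it. No list of input DNA was analysed here. Chromosome 6 was in the sample state over 130 Mb (88.7%) in iTSC_4F_1, with a longest domain of 18.9 Mb. Chromosome 14 was in the sample state over 90.2 Mb (75.7%) in iTSC_4F_5, with a mean score of 0.208 (SD 0.273 over domains). Chromosome 11 was in the sample state over 81.6 Mb (68.7%) in iTSC_3F_14 and in the TSC_B state over 60.4 Mb (50.8%) in iTSC_4F_1. Chromosome X was in the TSC_B state over 143 Mb (88.5%) in iTSC_3F_14, but over 6.05 Mb in iTSC_4F_1, 5.78 Mb in iTSC_4F_5, 17.5 Mb in iTSC_3F_1 and 7.78 Mb in TSC_A. Chromosome Y was in the TSC_B state over 15.0 Mb (94.3%) in iTSC_3F_14 and in the sample state over 15.0 Mb (94.5%) in iTSC_4F_5. Its mean scores were -0.012 and 0.026, and 1 domain made up 13.1 Mb of it in iTSC_3F_14 and 13.0 Mb in iTSC_4F_5. Scores this near 0 cannot tell equal reads from no reads, so these states are no evidence of a difference on Y. No filled chromosome was left when only domains of at most 1 Mb were kept, and 4 were left without domains that overlapped the TSC_A list.

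**Figure D1:**
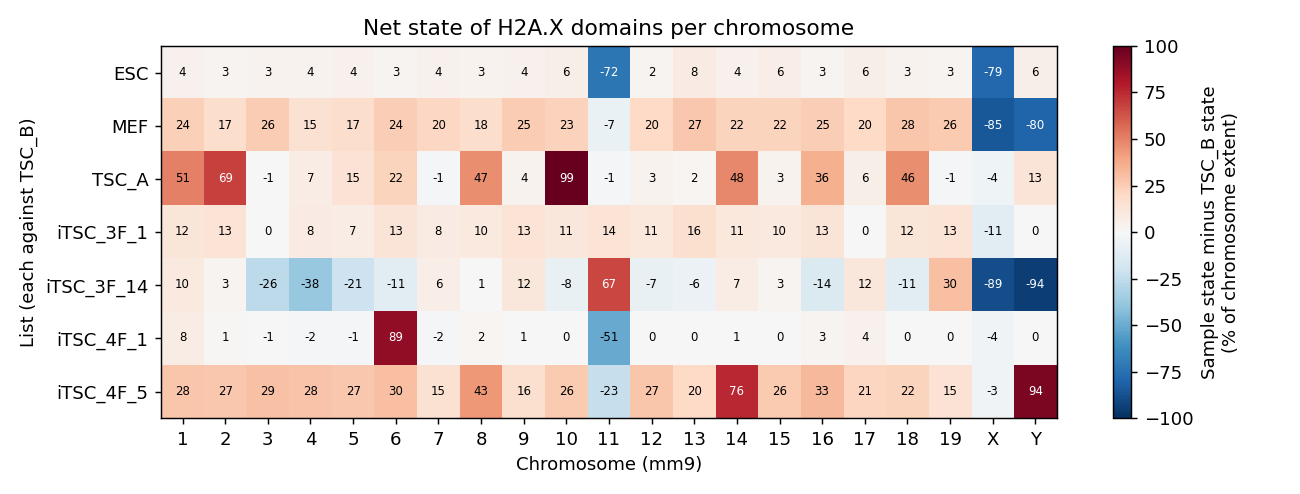
Net state of the H2A.X domains on each chromosome (mm9) for the 7 lists, as the percent of the chromosome's extent in the sample state minus the percent in the TSC_B state. Chromosome X is strongly negative in ESC, MEF and iTSC_3F_14, chromosome 10 is positive in TSC_A, and chromosome 6 in iTSC_4F_1.

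**Figure D2:**
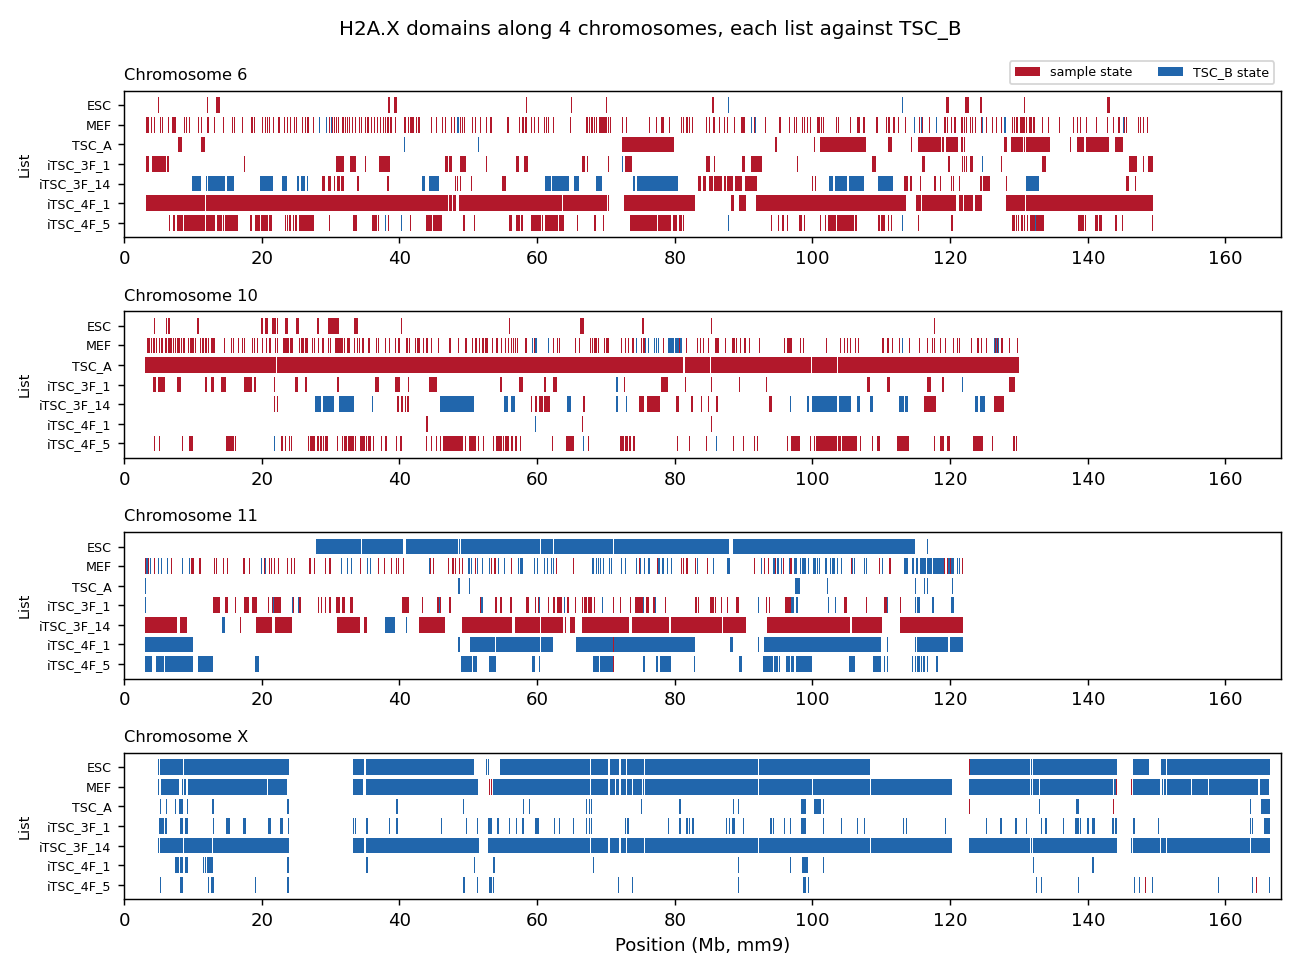
Domains along chromosomes 6, 10, 11 and X by position in Mb (mm9), 1 line per list, coloured by state. The TSC_B-state domains of ESC, MEF and iTSC_3F_14 fill most of X, and chromosome 11 carries the TSC_B state in ESC and iTSC_4F_1 but the sample state in iTSC_3F_14.

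Among nuclear domains of at least 5 kb, the 3 highest-scoring gains of ESC, of MEF and of TSC_A lay at the same places on the sex chromosomes, and 2 of them are given here. The domain at chromosome Y: 2847151 to 2902500 had a score of 181 in ESC, and the domains from the same start to 2903850 had 469 in MEF and 215 in TSC_A. Chromosome X: 120758851 to 120779100 had 82.3 in ESC, 272 in MEF and 115 in TSC_A, and neither region was a sample-state domain in iTSC_3F_1, iTSC_3F_14 or iTSC_4F_1. Among the TSC_B-state domains, the lowest scores included -47.3 in ESC at chromosome 11: 87862051 to 87867450, -52.3 in iTSC_4F_1 at chromosome 8: 125949601 to 125965800 and -68.7 in iTSC_4F_5 at chromosome 5: 104865301 to 104870700. A domain of the TSC_B state overlapped the chromosome 8 region in ESC, MEF, iTSC_3F_1 and iTSC_4F_5, and the chromosome 5 region in MEF, TSC_A and the other iTSC samples. The region at chromosome 1: 87484051 to 87490800 was in the sample state in iTSC_3F_14, with a score of 31.3, and in the TSC_B state in iTSC_4F_5, with -30.5. Sample-state domains of ESC and MEF overlapped it too. TSC_B-state domains of TSC_A, iTSC_4F_1 and the other 3-factor sample, iTSC_3F_1 (-23.8), also overlapped it, so iTSC_3F_14 stood apart from the other iTSC samples there. Scores are the domain caller's own values and rank domains only within a list.

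**Figure D3:**
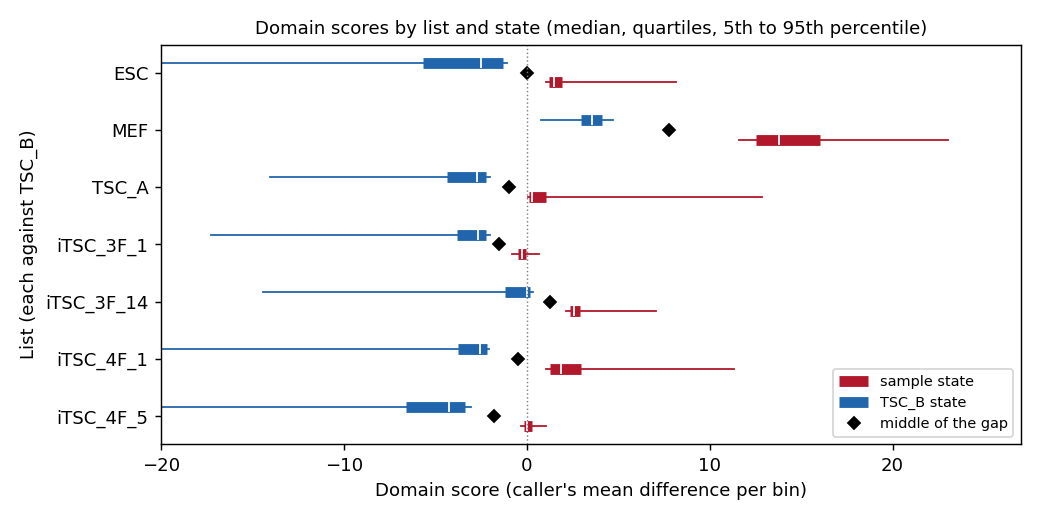
Domain scores (the caller's mean difference per bin) for each list and state without the mitochondrial genome, as median (white tick), quartiles (thick bar) and 5th to 95th percentile (line), with the middle of the gap between the states as a diamond. The gap lies near 0 in ESC, at 7.75 in MEF, at 1.27 in iTSC_3F_14 and at -1.80 in iTSC_4F_5.

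The next question was whether the same regions differed from TSC_B in different cells. On autosomes in the sample state, ESC and iTSC_3F_1 shared 22.6 Mb, 2.25 times the length expected by chance, and ESC and MEF shared 39.0 Mb, 1.67 times chance. MEF and iTSC_3F_1 shared 81.9 Mb, 1.36 times chance. TSC_A and iTSC_4F_5 shared 308 Mb (1.47 times), TSC_A and iTSC_4F_1 57.3 Mb (1.36 times), and both 4-factor samples shared 65.7 Mb (1.34 times). ESC and TSC_A shared 30.5 Mb (1.20 times), and MEF and iTSC_4F_1 43.6 Mb (1.07 times). These were the 8 of 21 pairs past the threshold, with adjusted p from 3.82e-05 to 0.0221 in the one-sided permutation test by circular shifts. 9 pairs had an unadjusted p under 0.05. The pair of 3-factor samples shared 56.0 Mb (1.16 times, adjusted p = 0.0797 in the permutation test). iTSC_3F_14 and iTSC_4F_5 shared 30.7 Mb, 0.320 times chance. In opposite states, the sample state of TSC_A and the TSC_B state of iTSC_3F_14 shared 180 Mb, 1.65 times chance. That fold is higher than the same-state fold of TSC_A and iTSC_4F_5, so the latter is no sign of a shared direction by itself. Among these 8 pairs, each pair with iTSC_4F_1 or iTSC_4F_5 lost its call under at least 1 alternative, as did ESC with iTSC_3F_1 and MEF with iTSC_3F_1. Where these calls were lost without a change of direction the folds were 1.03 to 2.26, and some exceeded those of all data, such as 1.44 for TSC_A and iTSC_4F_1 under 1 shift of the whole genome. With a mean posterior of at least 0.8, the fold was 0.759 for TSC_A and iTSC_4F_5 and 0.989 for MEF and iTSC_4F_1.

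In the TSC_B state, the highest folds joined TSC_A with 3 of the 4 iTSC samples. On autosomes TSC_A and iTSC_3F_1 shared 2.99 Mb, 21.9 times chance (7.71 Mb and 7.89 times over all chromosomes), TSC_A and iTSC_4F_5 2.84 Mb (6.59 times), and TSC_A and iTSC_4F_1 4.25 Mb (4.53 times). TSC_A and iTSC_3F_14 shared 0.844 Mb, 0.371 times chance. iTSC_3F_1 shared 4.09 Mb with iTSC_4F_5 (3.93 times) and 6.05 Mb with iTSC_4F_1 (2.65 times). The 4-factor samples shared 24.01 Mb (1.73 times), MEF and iTSC_3F_1 1.94 Mb (2.01 times), and MEF and iTSC_4F_1 16.1 Mb (1.65 times). These 8 of 21 pairs passed the threshold on autosomes, with adjusted p from 3.82e-05 to 0.0221 in the permutation test, and 8 had an unadjusted p under 0.05. With X and Y included 12 pairs passed. The pair of 4-factor samples and both pairs with MEF lost their calls under at least 1 alternative, with folds of 1.03 to 3.05 there. Those alternatives were run over all chromosomes. With all domains the folds there were 1.86 for the 4-factor samples, 1.09 for MEF and iTSC_3F_1, and 1.42 for MEF and iTSC_4F_1. ESC and iTSC_4F_1 shared 47.2 Mb, most of it on chromosome 11, which was 1.09 times chance once shifts stayed within chromosomes (adjusted p = 0.508 in the permutation test). MEF and iTSC_3F_14 shared 0.965 Mb, 0.0861 times chance. All lists were called against the same TSC_B library, so an overlap above chance can come from that library alone. Its part could not be simulated from domain lists, and the overlap with the TSC_A list stands in for it.

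**Figure D4:**
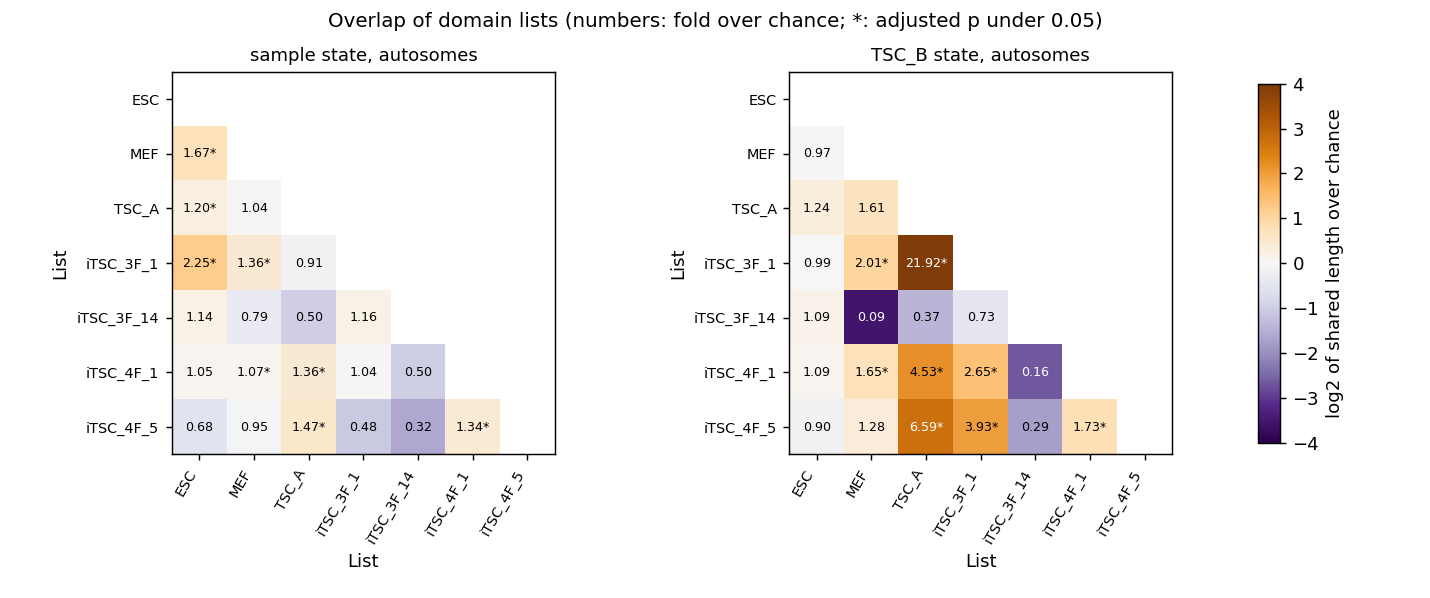
Overlap of each pair of lists on autosomes, left for the sample state and right for the TSC_B state. Colour gives the log2 of shared length over the mean of shifted placements and the printed number the fold, with a star where the adjusted p is under 0.05, and the highest fold is that of TSC_A and iTSC_3F_1 in the TSC_B state, at 21.9.

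To see how far the differences of fibroblasts from TSC_B were also present in induced cells, the share of MEF domain length found in each iTSC list was taken. The iTSC samples held 15.1% ± 8.26 (SD, n = 4) of the length of the MEF sample-state domains, against 15.2% by chance. The share was 14.4% in iTSC_3F_1 (1.36 times chance), 11.6% in iTSC_3F_14 (0.792 times), 7.69% in iTSC_4F_1 (1.07 times) and 26.8% in iTSC_4F_5 (0.951 times). iTSC_3F_1 and iTSC_4F_1 passed the threshold. TSC_A held 27.7%, 1.04 times chance (adjusted p = 0.117 in the permutation test), and ESC 7.004%, 1.70 times chance. On autosomes the MEF sample state also overlapped the opposite, TSC_B state of iTSC_3F_1 (5.11 Mb, 1.65 times chance) and of iTSC_4F_5 (6.71 Mb, 1.41 times), both past the threshold. With iTSC_4F_1 and iTSC_3F_14 the opposite-state folds were 0.964 and 0.776. For TSC_B-state domains on autosomes the iTSC share was 8.22% ± 9.22 (SD, n = 4), against 8.76% by chance. This mean rests mainly on iTSC_4F_1, with 21.4%, while the other samples held from 1.29% to 7.58%. iTSC_3F_1 (2.01 times chance) and iTSC_4F_1 (1.65 times) passed the threshold, and iTSC_3F_14 was at 0.0861 times.

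Of the length of the ESC sample-state domains, the iTSC samples held 16.03% ± 7.77 (SD, n = 4), against 14.4% by chance. iTSC_3F_1 held 23.4% (2.25 times chance) and was the only iTSC sample past the threshold, while iTSC_3F_14 held 15.1% (1.14 times), iTSC_4F_1 5.53% (1.05 times) and iTSC_4F_5 20.1% (0.696 times). With scores at least 1.5 from the middle of each list's gap, the fold of iTSC_3F_1 was 2.26 with an adjusted p of 0.0655 in the permutation test. MEF held 41.0% and TSC_A 32.8% of the same length. On autosomes the ESC sample state also overlapped the opposite, TSC_B state of iTSC_3F_1 (2.02 Mb, 4.16 times chance), iTSC_4F_5 (3.55 times) and iTSC_4F_1 (2.52 times). These opposite-state overlaps passed the threshold too, while that with iTSC_3F_14 was at 0.422 times. Overlap of ESC gains with iTSC_3F_1 above chance was thus seen in both states. Of the ESC TSC_B-state domains on autosomes the iTSC samples held 19.9% ± 24.1 (SD, n = 4), against 19.4% by chance, and no sample passed the threshold. This mean rests mainly on iTSC_4F_1, with 53.9% (49.6% by chance), while the other samples held from 2.17% to 20.2%.

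Few regions differed from TSC_B in all 4 iTSC samples. No chance level was computed for regions shared by all 4, so they are given by position and not as a feature of iTSC. Of the 6 pairs of iTSC samples on autosomes, 1 passed the threshold in the sample state and 3 in the TSC_B state. In the sample state there were 6 regions shared by all 4, 535 kb in all. The longest was at chromosome 11: 70983001 to 71147700 (165 kb), which was a domain of this state neither in ESC nor in TSC_A. Chromosome 6: 38376451 to 38483100 (107 kb) was also in the sample state in ESC over its whole length, chromosome 14: 53340301 to 53439100 (98.8 kb) in MEF, and chromosome 6: 70243201 to 70332300 (89.1 kb) in both. The others were chromosome 7: 26863201 to 26906100 (42.9 kb), which was in the sample state in TSC_A and in the TSC_B state in MEF, and chromosome 15: 73116001 to 73148400 (32.4 kb). In the TSC_B state there were 35 regions, 1540 kb in all, of which 25 (1394 kb) lay on chromosome X, 8 (140 kb) on autosomes and the other 2 on the mitochondrial genome. Of this length 94.1% was in the TSC_B state in the TSC_A list too, and 89.6% in ESC. The longest were chromosome X: 98586451 to 99010350 (424 kb), chromosome X: 8159401 to 8547500 (388 kb) and chromosome 3: 93565801 to 93675150 (109 kb). The last was in the TSC_B state in TSC_A but in the sample state in ESC and MEF.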

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

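This comparison was chosen after the results were seen. Chromosome 11 had opposite net states in the iTSC samples made with 3 and with 4 factors. Its length in the sample state minus its length in the TSC_B state was 16.1 Mb in iTSC_3F_1 and 79.7 Mb in iTSC_3F_14, but -60.2 Mb in iTSC_4F_1 and -27.0 Mb in iTSC_4F_5. The difference was not tested. The sample-state domains of iTSC_3F_1 there had a mean score of -0.535 (SD 0.425 over domains), meaning fewer reads than TSC_B. They are gains only relative to the middle of that list's gap, -1.50. The main state had a mean score above 0 only in iTSC_3F_14, at 2.76, against -2.35 in iTSC_4F_1 and -3.25 in iTSC_4F_5. At a mean posterior of at least 0.8 the whole iTSC_3F_1 list covered 3.81 Mb, so its net length of 16.1 Mb rests on domains of lower posterior. Of 21 chromosomes looked at, 1 had such a split, and random signs would give it on 12.5% of chromosomes.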

How the results depend on the processing

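The alternatives named in the methods as added after seeing the data (at most 1 Mb, mean posterior, distance from the gap, pairs without MEF) were not planned. The planned tests of gene lists and of domain position relative to genes, with their alternatives, were not run, since no mm9 annotation was used here. A minimum of 5 kb kept every result within the limits set for the same value, and so did joining for number, length, shares and filled chromosomes (overlap of pairs was not run with it). Where an alternative removes domains, fewer domains and less length follow from its construction. For all other changes below the cause was not tested. No paired analysis was possible because the iTSC groups share only 1 sample number. The unknown depth limits every comparison of numbers between lists. Of the values for the 20 pairs past the threshold under alternatives, 176 kept direction and call, 24 lost the call and 4 reversed.

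The pooled median of the absolute score, 13.2, was set by MEF. At or above it the domain number was 34 in ESC, 19270 in MEF, 33 in TSC_A, 30 in iTSC_3F_1, 38 in iTSC_3F_14, 30 in iTSC_4F_1 and 57 in iTSC_4F_5. The covered length was 0.589, 206, 0.514, 0.238, 0.292, 0.257 and 0.278 Mb in the same order, and the 3-factor minus 4-factor difference reversed to -0.00255 Mb. The iTSC share of sample-state length became 0.0172% for MEF and 0.926% for ESC, 0 chromosomes were filled, and 21 of 21 pairs passed in the TSC_B state.

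On autosomes only, ESC covered 183 Mb, 8 chromosomes were filled, and the TSC_B-state fold turned below chance for ESC with MEF (0.971) and with iTSC_3F_1 (0.995). Without domains overlapping the TSC_A list, 404 domains (128 Mb) were left in ESC, 267 (113 Mb) in iTSC_4F_1 and 1505 (335 Mb) in iTSC_4F_5, with 4 chromosomes filled. Of the 15 pairs then left, 10 passed in the sample state and 6 in the TSC_B state, against 5 and 8 of the same pairs with all domains. With domains of at most 1 Mb, covered length was 96.7 Mb in ESC, 72.2 in TSC_A, 225 in iTSC_3F_14, 38.4 in iTSC_4F_1 and 367 in iTSC_4F_5, 0 chromosomes were filled, and 15 sample-state pairs passed.

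At a mean posterior of at least 0.8, the domain number was 157 in ESC, 10890 in MEF, 174 in TSC_A, 99 in iTSC_3F_1, 504 in iTSC_3F_14, 229 in iTSC_4F_1 and 324 in iTSC_4F_5, and the 3-factor minus 4-factor number reversed to 25. Covered length was 258 Mb in MEF, 247 in TSC_A, 3.81 in iTSC_3F_1 and 40.6 in iTSC_4F_5, and the iTSC share of MEF sample-state length was 4.03%. The sample-state fold reversed to 0.989 for MEF with iTSC_4F_1 and to 0.759 for TSC_A with iTSC_4F_5. With scores at least 1.5 from the gap's middle, 357 domains (41.5 Mb) were left in ESC and 254 (149 Mb) in TSC_A. In iTSC_3F_1 292 (38.1 Mb) were left, and in iTSC_3F_14 361 (234.7 Mb). A wide gap leaves less to remove, and all 441 domains stayed in iTSC_4F_1 and 32997 in MEF. With this setting 8 chromosomes were filled. The covered-length difference reversed to -310 Mb, which follows at least partly from the widths of the gaps.

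Counting domains that overlap by at least 1 bp gave 14 sample-state pairs past the threshold, and by at least 50% gave 16. By 1 bp the iTSC share of ESC domains was 25.7% in the sample state and 53.2% in the TSC_B state. Without the MEF list 5 of 15 sample-state pairs passed. Leaving out 1 iTSC sample at a time moved the 3-factor minus 4-factor difference between -189 and 489 Mb in covered length, with -92.8 Mb without iTSC_4F_1, and between -1232 and 593 in number. Over all chromosomes, the same step moved the iTSC share of MEF length between 11.2% and 17.6% in the sample state and between 7.14% and 28.1% in the TSC_B state, and that of ESC length between 13.6% and 19.5% and between 14.6% and 31.7%. Both lowest TSC_B-state values were those without iTSC_3F_14, against 22.2% for MEF and 25.97% for ESC with all 4 samples.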

Other observations

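All tests in this part were chosen after the results were seen. The mitochondrial genome, which carries no nucleosomes and so no H2A.X, was a single domain in 6 of the 7 lists. It was in the TSC_B state in ESC (score -191), MEF (-280), iTSC_3F_1 (-210), iTSC_3F_14 (-215) and iTSC_4F_5 (-70.6), and in the sample state in TSC_A (411). In iTSC_4F_1 it was split, with 22.3 from 2701 to 12150 and -71.1 and -52.9 on either side. The bounds of the score gap lay within 0.01 of a whole number in 9 of 14 cases, where chance gives a share of 0.02 (exact binomial p = 9.36e-13).

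Domains of opposite state also coincided. Of 42 pairs of a sample state with another list's TSC_B state on autosomes, 14 passed the threshold. The sample state of ESC and the TSC_B state of TSC_A shared 2.41 Mb, 4.43 times chance, and with the TSC_B state of iTSC_3F_1 it shared 2.02 Mb, 4.16 times chance. The sample state of iTSC_3F_14 and the TSC_B state of MEF shared 46.0 Mb, 2.28 times chance. The sample state of TSC_A and the TSC_B state of iTSC_3F_14 shared 180 Mb, 1.65 times chance. Each of these had an adjusted p of 4.67e-05 in the permutation test.

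Chromosome X was in the TSC_B state over most of its length in ESC, iTSC_3F_14 and MEF. Few reads on X in both libraries would put its score near 0. The mean X score was -1.16 (SD 0.404) in iTSC_3F_14 and 3.46 (SD 0.286) in MEF. Both lay further from 0 than their SD, so, as the score is read here, X was not without reads in both libraries. How near to 0 counts was set after the scores were seen, and reads per bin are unknown. Low reads in both libraries with a small difference between them are therefore not excluded. Few reads on X were not tested in ESC, whose list holds no TSC_B-state score above -1.02. In MEF the score lay above 0 but below the middle of that list's gap, 7.75, so X was lower there only relative to the rest of the genome. The state covered most of 80.1% of the 161 windows of 1 Mb in ESC, 90.7% in iTSC_3F_14 and 88.2% in MEF. Fewer copies of X per cell than in TSC_B is a candidate explanation, and it cannot be told apart from less H2A.X along all of X, because no list of input DNA was analysed here.

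Many autosomal regions were in the sample state in iTSC_4F_5 and in the TSC_B state in iTSC_3F_14. They covered 313.5 Mb, 2.45 times chance, or 47.0% of the former and 74.7% of the latter. Whether iTSC_3F_14 had fewer raw reads than TSC_B there and iTSC_4F_5 more cannot be decided from the scores. These belong to whole domains, which extend beyond the shared regions. The median scores of all autosomal domains of these states were near 0 too, at 0.015 in iTSC_4F_5 and 0.061 in iTSC_3F_14. The mean score of the domains, weighted by their shared length, was -0.070 (SD 0.207) in iTSC_4F_5 and 0.121 (SD 0.183) in iTSC_3F_14, a difference of -0.191. Scores this near 0 lie above the middle of the gap in iTSC_4F_5 (-1.80) and below it in iTSC_3F_14 (1.27), so few reads in every library may give both states, as may equal reads in libraries of unequal depth. Chromosome Y, with scores of 0.026 in iTSC_4F_5 and -0.012 in iTSC_3F_14, showed the same opposition, and there equal reads and no reads cannot be told apart. Opposite changes stay open, whether in raw reads or only after scaling for depth, as the scores are those of whole domains and reads per library are unknown.

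On autosomes, 135 regions (18.8 Mb) were in the TSC_B state in at least 3 of the ESC and iTSC lists, and 9.63% of their length was in this state in the TSC_A list. Chromosome 11 held most of that length in long stretches and was left out, which left 87 regions (2.0 Mb). Of the length of these, 55.8% was in the TSC_B state in the TSC_A list as well, against 0.795% in shifted placements, 70.2 times chance (permutation p = 1e-05, the smallest they can give). High reads in the TSC_B library itself may therefore account for that part. H2A.X specific to trophoblast stem cells was not tested and stays open throughout, as the lists give TSC_A only relative to TSC_B. The longest of the regions with no TSC_B-state domain of TSC_A were chromosome 17: 27369901 to 27530100 (160 kb) and chromosome 18: 40680901 to 40786200 (105 kb).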
